A study of Homo sapiens with 10 samples.

How the data were processed

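Per the labels, HEK 293T cells, an established human kidney line, carrying FLAG-tagged eIF4A were treated for 1 h with vehicle (DMSO), 20 nM silvestrol or 20 nM CR-1-31-B and then crosslinked with ultraviolet light (254 nm, 400 mJ/cm2). RNA fragments bound to the tagged protein were recovered with an anti-FLAG antibody and sequenced by enhanced crosslinking and immunoprecipitation (eCLIP). The design holds 3 libraries each for DMSO, silvestrol and CR-1-31-B, numbered 1 to 3, and 1 input library (number 2) made without antibody.

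The deposited values are read counts, 1 file per library, for each of 39472 gene symbols in 7 classes named in the file headers (5' leader, CDS, 3'UTR, ncRNA, transcript, Pseudogene and LINC). Reads were trimmed with cutadapt and aligned with Bowtie 1.1, per the submitters' processing notes. The genome build, the annotation, the handling of PCR duplicates, the use of strand and the rule for counting a read were not given in the sources used here. Counts of near-identical copies, of overlapping genes and of antisense genes are therefore uncertain, which concerns ribosomal protein mRNAs with processed pseudogenes, multicopy small nuclear RNAs and mitochondrial-rRNA-like genes in particular. A pair of a symbol and a class is called a feature below. Each file held 1 blank line without values, which was left out. No pair of libraries of a group repeated the same counts (chi-square per degree of freedom from 4.66 to 10.4).

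Totals ranged from 858733 to 1804732 counts in the anti-FLAG libraries, and the input library held 2193699. Shares of a single library are given with 95% exact (Clopper-Pearson) intervals, and a count of 0 is read against a floor of 3 counts. Without molecular identifiers these intervals and floors cover counting error only.

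The 9 anti-FLAG libraries were compared with edgeR 4.0.16 (R 4.3.3). The steps were filterByExpr by group, TMM factors, quasi-likelihood fits and tests, and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold and no fold minimum. Of all features, 24713 were tested. The contrasts were silvestrol against DMSO, CR-1-31-B against DMSO, CR-1-31-B against silvestrol, and the mean of both rocaglates against DMSO. A feature past the threshold is said to be called. CPM of single features in these comparisons use the TMM-scaled library sizes. All p-values concern these libraries alone, since the labels do not say whether the numbers mark separate cultures. Fisher's exact tests count features as independent units, so their p-values do not measure the spread between libraries.

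The labels give every anti-FLAG group the numbers 1 to 3. Whether these pair the libraries was checked from deviations of log2 CPM (prior count 2) from the group means, before any fit was compared. The 9 same-number pairs correlated at 0.102 to 0.263 (mean 0.191), the other pairs at -0.203 to 0.0163, and each of the 9 libraries correlated best with a library of its own number. All same-number pairs thus passed the preset limit of 0.1 and the numbers were taken as pairs, although the lowest pair was borderline (0.0908 with a prior count of 0.5). The pairing comes from the data and not from a statement in the labels. The fit without the number as a block had been fixed as the main one, and the blocked fit is given beside it where it changes a call or moves a count of calls by over 1.5 times.

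On simulated counts with 100 features changed 2-fold and 100 changed 4-fold among 24713, the edgeR step recovered 28 of the 4-fold changes for silvestrol against DMSO, 29 for CR-1-31-B against DMSO, 25 for CR-1-31-B against silvestrol and 41 for both rocaglates against DMSO. At 2-fold it recovered 1, 1, 1 and 3 in the same order, and at most 1 unchanged feature was called in a contrast. With the block the 4-fold recoveries were 27, 31, 21 and 40. A planted gene list was called (camera adjusted p = 1.2e-24), and no other set was. The simulated features were drawn independently and without differences between the library numbers. These runs therefore do not show how the set tests behave under correlation, or what the block gains.

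Gene lists, 22 in number, were fixed before the data were examined and tested per class with limma's camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01. Lists with at least 5 tested members in a class gave 56 sets per contrast, and adjustment was over these sets. Camera compares a set with the other features of its class, so its direction is relative to that class. It was repeated with an estimated correlation, and fry, which asks whether a set's members move one way on balance, was run beside it. Members past the threshold are counted over all features and adjusted over the list alone. The lists of initiation factors and of other mRNAs with a 5' terminal oligopyrimidine (TOP) tract share 6 genes, and the oncogenic and immediate early lists share 1, MYC. The initiation factor list also holds inhibitors of initiation (PDCD4 and EIF4EBP1). Whether each of the 531 genes of the KRAB zinc finger list has a KRAB domain was not checked.

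Features named in the text were chosen by a rule fixed before the data were examined. For each treatment contrast these are the 10 called features with the highest and the 10 with the lowest fold change, among those with a mean count of at least 50 whose treated libraries all lie on one side of the controls. With fewer than 5 calls, the 10 smallest p-values are given as values. For each list up to 4 called members are named, or the 2 most abundant if none is called. EIF4A1, EIF4A2, EIF4A3 and MYC are always named, and for the input comparison the 10 highest and 10 lowest ratios. Other features are marked as chosen after their values were seen. Some features that meet the rule are not reported here.

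Shares of counts per class were compared by exact two-sided permutation tests, where 3 against 3 libraries cannot give a p under 0.1 and 6 against 3 cannot give one under 0.0119. Chance agreement between contrasts that share the DMSO libraries was estimated from 20 simulations of unchanged groups, repeated for each setting in which the correlation was recomputed. Sequences came from GENCODE release 29 transcripts, 1 per gene (19492), used by symbol only. Of the 39472 symbols, 18855 matched directly and 427 through an older symbol, and 94.7% of the tested leaders had a sequence. The density of all-purine 6-mers was counted per 100 nt in leaders of at least 20 nt, and the highest 20% were tested with camera against the rest. The single input library allows no test. DMSO was compared with it as log2 ratios of plain CPM with 1 CPM added, over 26746 features with at least 10 counts, and list medians are given as percentiles among 10000 random lists matched on mean expression in 20 bins.

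The alternatives covered RLE, upper quartile and library size scaling, other count filters, DESeq2 1.42.0, limma voom, the replicate block, the groups of a contrast alone, a threshold of 0.1, counts summed per gene and leaving out each library. Libraries were left out of the fit without the block, and of the fit with it only for the JUN leader between the compounds. Without the block the pairing by number is ignored, so a call lost in this way may reflect the pairing or an unstable feature. Shares, plots and exact tests used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Peaks and coordinates were not analysed here, because the files give counts per symbol and no build.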

Results

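RNA bound by FLAG-tagged eIF4A, the RNA helicase that prepares mRNA 5' ends for ribosome loading, was profiled by eCLIP in HEK 293T cells after 1 h with vehicle (DMSO) or with 1 of 2 rocaglates, silvestrol and CR-1-31-B, each at 20 nM. Rocaglates are small molecules that act on eIF4A and its RNA. Each condition had 3 libraries, and 1 input library made without antibody gave the background. The DMSO libraries held 1071262, 1074588 and 943310 counts, the silvestrol libraries 1804732, 1004145 and 858733, and the CR-1-31-B libraries 1610372, 1279001 and 915817, in the order of their numbers 1 to 3. The input library held 2193699 counts. Counts were given per gene for the 5' leader, the coding sequence (CDS), the 3'UTR and 4 classes of other RNA, and 24713 features (a gene in 1 class) were tested, of which 7122 were 5' leaders, 8413 CDS and 6712 3'UTRs.

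The share of counts in each transcript part describes where the crosslinked counts fell in each condition. Shares and CPM are relative, so a higher share in 1 part lowers the others without any loss of binding there. RNA levels were not measured per treatment, so changes in binding and in abundance cannot be told apart. In DMSO, 5' leaders took 22.7% ± 1.80 (SD, n = 3) of the counts, against 7.57% in the input library (95% Clopper-Pearson interval 7.53% to 7.60%). With silvestrol the leader share was 30.8% ± 3.16 (n = 3) and with CR-1-31-B 30.2% ± 6.49 (n = 3). The 3'UTR share was 25.7% ± 1.49 in DMSO, 20.0% ± 1.27 with silvestrol and 19.6% ± 3.66 with CR-1-31-B (n = 3 each), while the CDS share was 32.9%, 30.4% and 33.2%. Across both rocaglates the leader share was 7.78 percentage points above DMSO (exact permutation p = 0.0476, adjusted p = 0.35 over 28 comparisons of shares), with 5 of 6 rocaglate libraries above all 3 DMSO libraries. The 3'UTR share was lower in 6 of 6 rocaglate libraries (mean difference -5.93 points, exact permutation p = 0.0119, the smallest that 6 against 3 libraries can give, adjusted p = 0.167). The 3'UTR of 1 gene, HINT3, held 4.03% of all counts in DMSO, 1.86% with silvestrol and 1.20% with CR-1-31-B, a difference of -2.49 of the -5.93 points for both rocaglates. The other 3'UTRs differed by -3.44 points of all counts (exact permutation p = 0.119, lower than all DMSO libraries in 4 of 6). With the HINT3 3'UTR counts also taken out of the total, the 3'UTR share differed by -4.05 points (exact permutation p = 0.0714, lower than all DMSO libraries in 5 of 6). The leader share then differed by 7.30 points (exact permutation p = 0.0595). These measures were added after the data were seen. Neither the leader nor the 3'UTR difference passed the correction over the 28 comparisons. The 3 against 3 comparisons among these cannot give a p under 0.1. An exact permutation p = 0.0119 could therefore pass only if all 7 classes reached it together, so this correction could hardly be passed and decides little. Against the DMSO library of the same number the leader share was higher in 6 of 6 rocaglate libraries, by at least 4.47 points with silvestrol and at least 2.10 points with CR-1-31-B. Permuted within numbers, the exact permutation p = 0.0370 was the smallest of 27 splits, for leaders as for 3'UTRs. The LINC (-0.216 points) and transcript (-0.184 points) classes, each a small share, gave the same value. Without the numbers LINC had an exact permutation p = 0.0119 (adjusted p = 0.167), as 3'UTRs did. CR-1-31-B library 3 had a leader share of 22.8%, within the range of the DMSO libraries (20.7% to 24.1%), and without that library the CR-1-31-B difference was 11.1 points in place of 7.43. A measure added after the data were seen counted within the leader, CDS and 3'UTR classes alone. The leader share was then 12.9% in the input, 27.9% in DMSO, 37.9% with silvestrol and 36.2% with CR-1-31-B. The input thus lay closer to DMSO than by all counts, of which ncRNA took 39.5% in the input and 15.9% in DMSO.

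**Figure D1:**
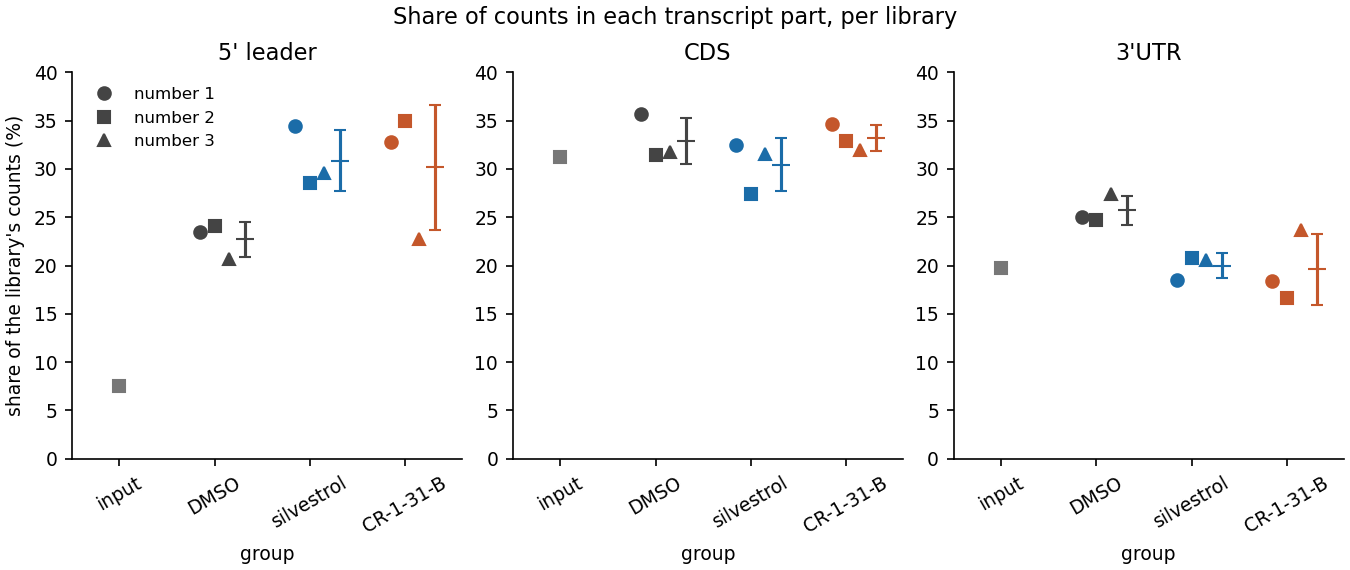
Share of each library's counts (%) in 5' leaders, CDS and 3'UTRs for the input library and the 3 libraries each of DMSO, silvestrol and CR-1-31-B, with marker shapes for the library number and bars for the group mean ± SD. The leader share was 7.57% in the input, 20.7% to 24.1% in DMSO, and above 28% in every rocaglate library except CR-1-31-B library 3 (22.8%).

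Fold changes of single features moved the same way. The median log2 fold change of the 7122 leaders was 0.40 with silvestrol and 0.35 with CR-1-31-B, with 70.4% and 67.6% of leaders above 0, and between 0.37 and 0.42 and between 0.31 and 0.37 over the 4 scalings tried. The 6712 3'UTRs had medians of -0.26 and -0.27, and the CDS features of -0.12 and -0.03. As classes, leaders moved up (camera adjusted p = 1.2e-16 for silvestrol and 7.3e-11 for CR-1-31-B) and 3'UTRs down (9.3e-07 and 1.6e-08) against all other features. With an estimated correlation none of these passed: for leaders, adjusted p = 0.154 with an estimated correlation for silvestrol and 0.330 for CR-1-31-B, and for 3'UTRs 0.357 and 0.330. Against all other features, the CDS class was lower with silvestrol (camera adjusted p = 0.0306; adjusted p = 0.357 with an estimated correlation), and the transcript class lower with CR-1-31-B (camera adjusted p = 0.0252; adjusted p = 0.803 with an estimated correlation). For both rocaglates together the leaders were up (camera adjusted p = 2.6e-16; adjusted p = 0.160 with an estimated correlation), the 3'UTRs down (5.1e-09; adjusted p = 0.301 with an estimated correlation) and the transcript class down (0.0379; adjusted p = 0.716 with an estimated correlation).

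**Figure D2:**
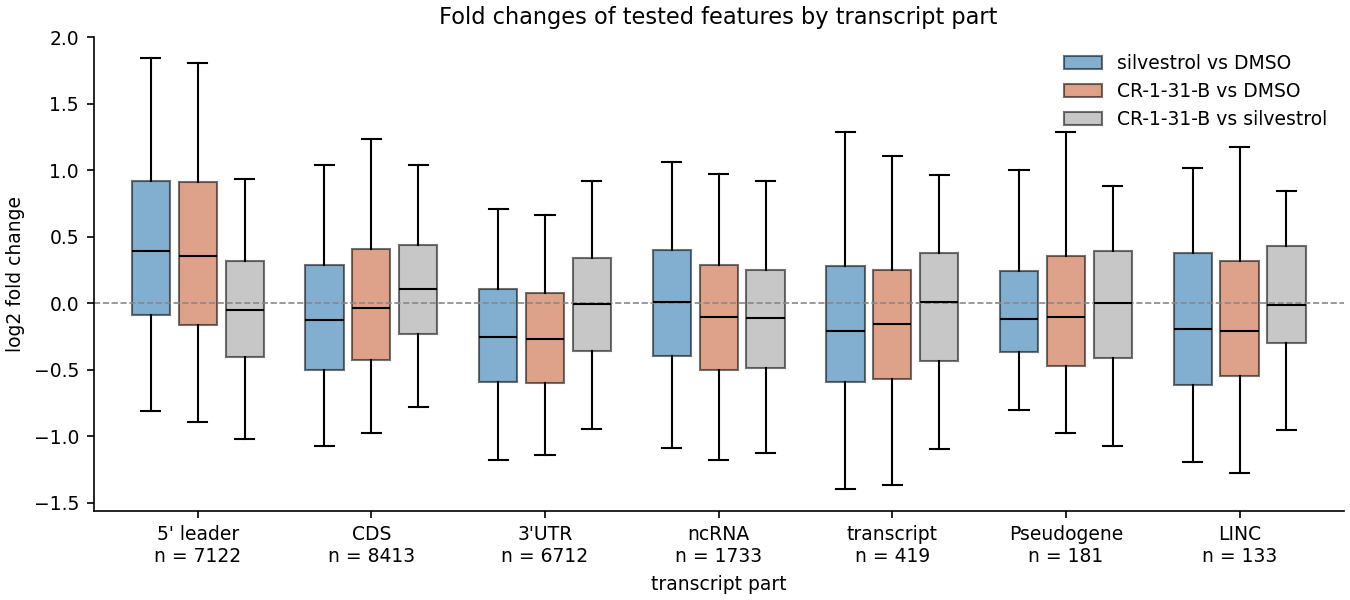
Log2 fold changes of the tested features in each of the 7 classes for silvestrol against DMSO, CR-1-31-B against DMSO and CR-1-31-B against silvestrol; boxes span the quartiles with the median as a line, and whiskers the 5th to 95th percentiles. Leaders had medians of 0.40 and 0.35 against DMSO and -0.05 between the rocaglates, and 3'UTRs -0.26, -0.27 and -0.01.

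Silvestrol against DMSO asks which RNA parts held relatively more or fewer anti-FLAG counts with this rocaglate. The 5' leader of POU3F2, a neural transcription factor, rose from 3.51 ± 2.13 to 76.6 ± 9.48 CPM (SD, n = 3 each), a log2 fold change of 4.40 (SE 0.66, edgeR adjusted p = 0.00381). The leader of the filamin gene FLNC rose from 12.3 ± 2.33 to 129 ± 6.32 CPM (log2 3.38, SE 0.42, adjusted p = 0.000972), and that of the protocadherin gene PCDH9 from 21.3 ± 8.02 to 237 ± 73.8 CPM (log2 3.46). The leader of CCND1, which encodes cyclin D1, rose from 9.96 ± 4.55 to 81.4 ± 0.605 CPM (log2 3.02, SE 0.44, adjusted p = 0.00381). The leader of the oncogene MYC rose from 116 ± 22.1 to 434 ± 80.6 CPM (log2 1.90, SE 0.34, adjusted p = 0.0168), whereas its CDS had a log2 fold change of 0.67 (adjusted p = 0.660) and was not called. Further leaders among the 10 highest were SNRNP25 (3.07), TAOK2 (2.66) and TPM3 (2.59), and the features outside leaders were the CDS of RPL41 (2.66) and the CNIH3 transcript (2.59). In each of these features the 3 silvestrol libraries all lay above the 3 DMSO libraries. Leaving out 1 library, TPM3 and CNIH3 lost their call without any 1 DMSO library or silvestrol library 1 (adjusted p up to 0.134), TAOK2 without DMSO library 1 or 3 or silvestrol library 1 (up to 0.101), and RPL41 CDS without DMSO library 2 or 3 or silvestrol library 1 (up to 0.0912).

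In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 63 features of 62 genes with silvestrol, and all 63 rose. Of these, 61 were 5' leaders, where leaders are 28.8% of the features tested (Fisher's exact odds ratio 76.1, p = 9.2e-31). With the replicate block the count was 316, of which 308 rose and 8 fell, and all 63 calls were among them. Leaders then made up 264 of the 308 (Fisher's exact odds ratio 15.4, p = 1.7e-97). The count changed with the library left out. It was 14, 7 and 4 without DMSO libraries 1, 2 and 3. Without silvestrol libraries 1, 2 and 3 it was 6, 100 and 29. Without CR-1-31-B libraries 1 and 3 it was 38 and 99. Leaving out a library changed both the spread and the features that passed the filter (27222 and 27258 tested in the last 2 fits), and these were not told apart. With only the silvestrol and DMSO libraries in the fit the count was 68. Limma voom called 74 with 50 of the 63 among them, and did not call POU3F2 (adjusted p = 0.360). The leaders of POU3F2, FLNC, PCDH9 and SNRNP25 were called in all 9 fits without 1 library. CCND1 was called in 8 (edgeR adjusted p = 0.0521 without DMSO library 3). MYC was called in 5 (edgeR adjusted p from 0.0614 to 0.181 without any 1 DMSO library or silvestrol library 1). Over these fits the log2 fold change was 2.80 to 3.46 for CCND1 and 1.80 to 2.12 for MYC.

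Among the fixed gene lists, cytosolic ribosomal protein leaders had a lower median than other leaders with silvestrol but a higher share of calls. Of 78, 4 rose (RPL18 with a log2 fold change of 2.23, RPL41 2.06, RPS15 1.90 and RPL24 1.87), none fell and 74 were not called, and adjusted over the list alone 8 rose and 1 fell. That is 5.13% of the list, against 57 of 7044 other leaders or 0.809% (Fisher's exact odds ratio 6.62, p = 0.00433), and with the block 8 of 78 against 256 of 7044 (odds ratio 3.03). Above 0 were 48.7% of the list and 70.6% of other leaders. Their median was -0.05, against 0.40 for other leaders, their mean was 0.04, and camera placed them below other leaders (adjusted p = 0.0326; adjusted p = 0.973 with an estimated correlation), so the signs of the median and mean differed. The list of oncogenic mRNAs known as sensitive to eIF4A inhibition had 2 of 27 leaders called, both higher (CCND1 and MYC), and 7 adjusted over the list alone. Called leaders of other lists were all higher. Of the initiation factor list these were PDCD4 (2.16) and EIF4EBP1 (2.66), which encode inhibitors of initiation and not initiation factors. Of the helicases it was DDX6 (2.39), and of the chaperones DNAJB6 (edgeR adjusted p = 0.0170). The list of hnRNP and SR proteins had HNRNPD (1.73), and the KRAB list had ZNF574 (2.76). Adjusted over the list alone these lists had 4, 1, 3, 4 and 1 higher leaders. TPM3 was the 1 called cytoskeleton leader of 26, and adjusted over the list alone 9 rose and 1 fell. Of 26 cell cycle and 26 proteasome leaders edgeR called 0 over all features, and 7 and 5 were higher adjusted over the list alone. Without any 1 DMSO library, silvestrol library 1 or 3, or CR-1-31-B library 1, PDCD4 was no longer called (adjusted p from 0.0741 to 0.345), nor were EIF4EBP1 (0.0730 to 0.328), HNRNPD (0.0658 to 0.341), RPL24 (0.0625 to 0.383), RPS15 (0.0666 to 0.251) and ZNF574 (0.0517 to 0.157). DDX6 was lost without DMSO library 2 or 3 or silvestrol library 1 or 3 (up to 0.177), DNAJB6 and RPL18 without DMSO library 2 or 3 or silvestrol library 1 (up to 0.198 and 0.165), and the RPL41 leader without any 1 DMSO library or silvestrol library 1 (up to 0.229).

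Camera ranked the CDS of several lists below other CDS features with silvestrol, whose median was itself -0.12, and no member was called over all features. The TOP mRNAs other than ribosomal proteins had a CDS median of -0.58 over 17 genes, against -0.12 for other CDS features (camera adjusted p = 0.00509; adjusted p = 0.973 with an estimated correlation). Medians were -0.71 over 17 glycolysis genes (0.00509), -0.43 over 31 cell cycle genes (0.00876), -0.47 over 30 chaperones (0.0266) and -0.37 over 72 nuclear-encoded oxidative phosphorylation genes (0.0266), the last with 1 member higher adjusted over the list alone and 0 in each of the others. Each of these had adjusted p = 0.973 with an estimated correlation. The 3'UTRs of 23 initiation factors had a median of -0.46 (0.0283), and 279 small nuclear, nucleolar and other non-coding RNAs one of 0.35 against -0.06 for other ncRNA (0.000841). Both had adjusted p = 0.973 with an estimated correlation, and fry called 0 sets. The number of sets past the threshold was 8, and 0 without DMSO library 1 (adjusted p from 0.0543 to 0.773), 13 without silvestrol library 1, 2 without silvestrol library 2 and 3 without silvestrol library 3. Only the TOP and oxidative phosphorylation CDS of the 8 sets were kept without silvestrol library 2 (the others from 0.0529 to 0.416), and only the glycolysis CDS and the small non-coding RNAs without silvestrol library 3 (the others from 0.0894 to 0.709). Without DMSO library 2 the ribosomal protein leaders (0.0626) and oxidative phosphorylation CDS (0.134) were lost, and without DMSO library 3 the small non-coding RNAs (0.522).

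CR-1-31-B against DMSO asks the same of the other compound. The leader of JUN, an immediate early transcription factor, rose from 416 ± 206 to 3047 ± 1653 CPM (SD, n = 3 each), a log2 fold change of 2.87 (SE 0.45, edgeR adjusted p = 0.00889). The POU3F2 leader rose from 3.51 ± 2.13 to 52.4 ± 40.4 CPM (log2 3.86, SE 0.65, adjusted p = 0.00893), and the leader of the immediate early gene IER2 from 14.8 ± 1.88 to 108 ± 80.8 CPM (log2 2.86, SE 0.53). The CCND1 leader rose to 63.9 ± 10.3 CPM (log2 2.68, SE 0.44, adjusted p = 0.00889) and the MYC leader to 406 ± 86.8 CPM (log2 1.80, SE 0.34, adjusted p = 0.0183), with the MYC CDS at 0.73 and not called. Other leaders among the 10 highest were C6orf106 (3.05), SLC2A1 (2.73), FZR1 (2.65) and RPL18 (2.62), and outside leaders the CNIH3 transcript (3.42) and the CDS of the zinc finger gene ZNF263 (3.06). The KRT32 transcript fell by 1.72 on the log2 scale, from 1202 ± 21.1 to 364 ± 95.7 CPM (SE 0.36, adjusted p = 0.0415), the only feature called lower.

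**Figure D3:**
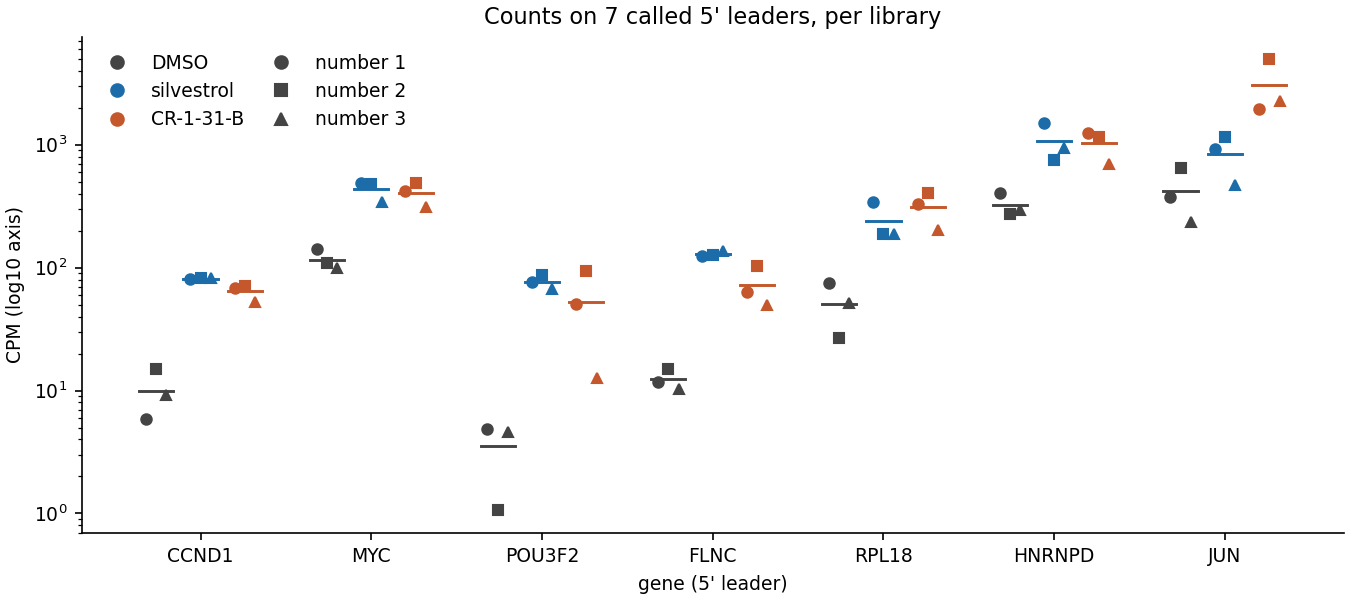
CPM on a log10 axis of 7 called 5' leaders in each library of DMSO, silvestrol and CR-1-31-B, with marker shapes for the library number and horizontal lines for the group mean. CCND1 lay between 5.87 and 14.9 CPM in DMSO and between 52.1 and 81.9 CPM in the 6 rocaglate libraries, and JUN at a mean of 847 CPM with silvestrol and 3047 CPM with CR-1-31-B.

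With CR-1-31-B, edgeR called 72 features, of which 71 rose and 1 fell, and 57 of the higher calls were leaders, 13 CDS and 1 a transcript (Fisher's exact odds ratio for leaders 10.1, p = 3.2e-19). Limma voom called 62 with 44 of the 72 among them, and did not call POU3F2 (adjusted p = 0.477). The replicate block gave 365 calls, 348 higher and 17 lower, with all 72 among them and 256 leaders among the 348 (Fisher's exact odds ratio 7.09, p = 1.2e-67). The count was 3 and 17 without DMSO libraries 1 and 2, 18 and 1 without CR-1-31-B libraries 1 and 2, 136 without silvestrol library 2 and 226 without CR-1-31-B library 3. Without DMSO library 3 edgeR called 0, with 1859 features at an unadjusted p under 0.05. None of the named calls of this contrast therefore held in all 9 fits. CNIH3 held in 8 (adjusted p = 0.0673 without DMSO library 3), JUN, CCND1 and ZNF263 in 6 (up to 0.111, lost without DMSO library 1 or 3 or CR-1-31-B library 2), RPL18 in 6 (up to 0.111, lost without DMSO library 2 or 3 or CR-1-31-B library 2), POU3F2 and IER2 in 5 (up to 0.111 and 0.234, lost without any 1 DMSO library or CR-1-31-B library 2), MYC in 4 (up to 0.201, lost without any 1 DMSO library or CR-1-31-B library 1 or 2) and KRT32 in 3 (up to 0.295, lost without any 1 DMSO or CR-1-31-B library). C6orf106 held in 5 (up to 0.111, lost without any 1 DMSO library or CR-1-31-B library 2), and SLC2A1 (up to 0.168) and FZR1 (up to 0.111) in 4, lost without any 1 DMSO library or CR-1-31-B library 1 or 2.

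Immediate early genes, which cells induce within minutes of a stimulus, were among the lists above their class with CR-1-31-B. With silvestrol their leaders had a median of 0.74, against 0.40 for all leaders, and the set did not pass. Of 18 leaders 3 rose (JUN, IER2 and MYC) and 15 were not called, with 6 higher adjusted over the list alone, and their median was 1.14 against 0.35 for other leaders (camera adjusted p = 0.00355; adjusted p = 0.895 with an estimated correlation). With the block 6 rose. In the CDS of 17 of these genes 0 were called over all features (edgeR) and 4 rose adjusted over the list alone, with a median of 0.73 against -0.03 (camera adjusted p = 0.000766; adjusted p = 0.895 with an estimated correlation). Their 13 3'UTRs had 0 called and 1 higher adjusted over the list alone, with a median of 0.33 against -0.27 (camera adjusted p = 0.000766; adjusted p = 0.895 with an estimated correlation). This set did not pass without DMSO library 3 (0.183) or CR-1-31-B library 2 (0.297). The CDS of 149 KRAB zinc finger genes had a median of 0.31 against -0.04 (camera adjusted p = 0.000766; adjusted p = 0.895 with an estimated correlation), with ZNF263 called and 2 higher adjusted over the list alone. The 213 KRAB 3'UTRs had a median of -0.11, below 0 but above the -0.28 of other 3'UTRs (camera adjusted p = 0.0404; adjusted p = 0.895 with an estimated correlation). They did not pass without any 1 DMSO library, silvestrol library 2 or CR-1-31-B library 3 (0.0529 to 0.428). Among the 205 leaders of the KRAB list ZNF574 (edgeR adjusted p = 0.0117) and ZNF398 (1.81) rose, with 8 higher adjusted over the list alone. ZNF574 was lost without any 1 DMSO library or CR-1-31-B library 1 or 2 (up to 0.111), and ZNF398 without these or silvestrol library 3 (lowest where lost 0.0596).

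Ribosomal protein leaders again lay below other leaders with CR-1-31-B, at a median of -0.23 against 0.36 over 78 (camera adjusted p = 0.000766; adjusted p = 0.895 with an estimated correlation). Of these RPL18 (2.62) and RPL24 (1.89) rose and 76 were not called, and adjusted over the list alone 4 rose and 1 fell. Of 7044 other leaders 55 rose (Fisher's exact odds ratio 3.34, p = 0.129). With the block 4 rose (against 252 of 7044 other leaders, Fisher's exact p = 0.364) and 2 fell, and adjusted over the list alone 7 rose and 8 fell. The CDS of RPL41 rose (2.25), as did the leaders of HNRNPD (1.68) and TPM3 (2.32). RPL41 CDS and TPM3 were lost without any 1 DMSO library or CR-1-31-B library 1 or 2 (up to 0.192 and 0.195), and RPL24 and HNRNPD without these or silvestrol library 3 (up to 0.225 and 0.251). The CDS of other TOP mRNAs had a median of -0.57 (0.000665) and that of glycolysis genes -0.44 (0.0119), with 0 of 17 called in each, and the small non-coding RNAs one of 0.12 against -0.16 (0.000766). All 9 sets past the threshold had adjusted p = 0.895 with an estimated correlation, and fry called 0. Without DMSO library 3 or CR-1-31-B library 2 the small non-coding RNAs did not pass (0.655 and 0.181), nor glycolysis without CR-1-31-B library 3 (0.110). The block added the CDS of ribosomal proteins (block adjusted p = 0.0457), oxidative phosphorylation (0.0457), chaperones (0.0480) and cell cycle genes (0.0457), and for these 4 block adjusted p = 0.385 to 0.688 with an estimated correlation. Without CR-1-31-B library 1, 15 sets passed, and 6 without CR-1-31-B library 3. The immediate early leaders did not pass without DMSO library 3 (0.0839) or CR-1-31-B library 2 (0.0765), their CDS not without CR-1-31-B library 2 (0.0519), and the ribosomal protein leaders not without DMSO library 1 (0.274) or CR-1-31-B library 3 (0.110).

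CR-1-31-B against silvestrol asks whether anti-FLAG counts were spread differently over RNA parts with the 2 compounds. The JUN leader was at 3047 ± 1653 CPM with CR-1-31-B and 847 ± 347 CPM with silvestrol (n = 3 each), a log2 difference of 1.85 (SE 0.44) that was not called (edgeR adjusted p over 0.99). With the replicate block it was the 1 call of this contrast (log2 1.82, adjusted p = 0.00292). The JUN CDS differed by 1.26 and its 3'UTR by 0.80, both looked at after the leader had been seen and neither called. The MYC leader was not called (log2 -0.10, SE 0.33). Other features among the 10 with the smallest p, none of them a call, were the leaders of HDDC2 (-1.79), NDUFB8 (-2.12), CTNND1 (-1.58) and CTCFL (-4.11), the 3'UTRs of SIAE (-2.29) and MREG (4.32), and the CDS of TBCC (1.90) and CHCHD6 (2.09).

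Without the block edgeR called 0 features between the compounds, with 609 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. No list passed camera's threshold. With the block the immediate early genes passed, as leaders (block median 0.28 against -0.06, block adjusted p = 0.0149) and as CDS (block median 0.91 against 0.12, block adjusted p = 0.00881), both with adjusted p = 0.805 with an estimated correlation. Without the block the medians were 0.31 and 0.71. Adjusted over the list alone, 1 of their 18 leaders was higher. The CDS class as a whole lay above other features (median 0.11, camera adjusted p = 0.0204; adjusted p = 0.681 with an estimated correlation). Without 1 library the number of sets past the threshold was 0 without silvestrol library 1, 6 without silvestrol library 2, 2 without silvestrol library 3, 1 without CR-1-31-B library 2, and 3 without any other.

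Both rocaglates together against DMSO ask what the class of compounds does with more libraries. POU3F2 (log2 4.13, SE 0.62, edgeR adjusted p = 0.00437), FLNC (2.96), PCDH9 (2.87), CCND1 (2.85, SE 0.41, adjusted p = 0.00319), C6orf106 (2.74), SNRNP25 (2.57), FZR1 (2.55) and MFHAS1 (2.47) were among the highest leader fold changes, and the CNIH3 transcript rose too (adjusted p = 0.00319). MYC rose by 1.85 (SE 0.31, adjusted p = 0.00638) and was higher in 6 of 6 rocaglate libraries than in any DMSO library. The 3'UTR of HINT3, a single feature with 44290 ± 17132 CPM in DMSO, was at 20715 ± 6041 CPM with silvestrol and 13008 ± 5339 CPM with CR-1-31-B, and fell by 1.43 on the log2 scale (SE 0.32, adjusted p = 0.0436). The counts came without coordinates, so it could not be checked whether an overlapping or repeated RNA was counted in this 3'UTR. The HINT3 leader, looked at after this value was seen, rose by 2.69 (adjusted p = 0.0416), and held in 3 of 9 fits without 1 library (up to 0.185, lost without any 1 DMSO library, silvestrol library 1 or CR-1-31-B library 1 or 2). The KRT32 transcript fell by 1.31 (SE 0.30, adjusted p = 0.0479).

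For both rocaglates edgeR called 121 features, 119 higher and 2 lower, of which 99 were leaders and 19 CDS (Fisher's exact odds ratio for leaders 12.4, p = 6.4e-35). Limma voom called 106 with 75 of the 121 among them, and did not call POU3F2 (adjusted p = 0.319). The block gave 505, of which 469 rose and 36 fell, with all 121 among them. The count was 27, 15 and 7 without DMSO libraries 1, 2 and 3, 44, 209 and 80 without silvestrol libraries 1, 2 and 3, and 44, 45 and 287 without CR-1-31-B libraries 1, 2 and 3. POU3F2, FLNC, CCND1 and CNIH3 were called in all 9 fits, PCDH9 and SNRNP25 in 8 (adjusted p = 0.0888 without DMSO library 3 and 0.0530 without DMSO library 2), C6orf106, FZR1 and MFHAS1 in 7 (up to 0.102, 0.0888 and 0.0667, lost without DMSO libraries 2 or 3, 1 or 3, and 1 or 2), MYC in 7 (adjusted p up to 0.124, lost without DMSO library 2 or 3), and HINT3 and KRT32 in 3 (up to 0.323 and 0.229, HINT3 lost without any 1 DMSO library, silvestrol library 1 or 3 or CR-1-31-B library 2, and KRT32 without any 1 DMSO library, silvestrol library 3 or CR-1-31-B library 1 or 2). Counts and fold changes were tested without the block unless stated.

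The fixed lists were read the same way for both rocaglates together. Of 18 immediate early leaders 4 rose (JUN 1.95, JUNB 2.89, IER2 2.14 and MYC) and 14 were not called, with 6 higher adjusted over the list alone (median 0.75). Of 27 oncogenic leaders 2 rose, with 6 higher adjusted over the list alone (median 0.48). The initiation factor list had 2 of 26 leaders called, EIF5B (2.00) and the inhibitor EIF4EBP1 (2.54), and 4 adjusted over the list alone. The proteasome had 2 of 26, PSMD1 (2.08) and PSMC4, which was listed at 0 in the 3 DMSO libraries and at 13.4 and 14.8 CPM with the rocaglates, and 5 adjusted over the list alone. Chaperones (DNAJB6, 1.88) and helicases (DDX6, 2.11) each had 1 of 29, and 3 adjusted over the list alone. HNRNPD (1.70) rose of 33 hnRNP and SR leaders, with 7 adjusted over the list alone. TPM3 (2.46) rose of 26 cytoskeleton leaders, with 6 higher and 1 lower adjusted over the list alone. ZNF574 (2.88) rose of 205 leaders of the KRAB list, with 9 higher adjusted over the list alone. Many of these calls were lost when 1 library was left out of the fit without the block, which ignores the pairing by number. JUNB and IER2 held in 2 of 9 fits without 1 library (adjusted p up to 0.230 and 0.238), both lost without any 1 DMSO library, silvestrol library 1 or CR-1-31-B library 1 or 2, and also JUNB without silvestrol library 3 and IER2 without silvestrol library 2. EIF5B, EIF4EBP1, PSMD1 and PSMC4 held in 3 (up to 0.191, 0.185, 0.221 and 0.184, lost without any 1 DMSO library, silvestrol library 1 or CR-1-31-B library 1 or 2). JUN held in 4 (up to 0.229, lost without any 1 DMSO library, silvestrol library 1 or CR-1-31-B library 2), HNRNPD in 4 (up to 0.185, lost without any 1 DMSO library, silvestrol library 1 or CR-1-31-B library 1) and DNAJB6 in 4 (up to 0.218, lost without DMSO library 2 or 3, silvestrol library 1 or CR-1-31-B library 1 or 2). DDX6, ZNF574 and TPM3 held in 7 (up to 0.184, 0.0974 and 0.110), the first 2 lost without DMSO library 2 or 3 and TPM3 without DMSO library 1 or 3.

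Other lists had 0 leaders called for both rocaglates by edgeR over all features. Adjusted over the list alone, 8 of 26 cell cycle leaders were higher (median 0.53; MCM7 at 1.16 with adjusted p = 0.124 and block adjusted p = 0.0193), 2 of 12 stress-response leaders with upstream reading frames (median 0.61; ATF4 at -0.18), 1 of 16 aminoacyl-tRNA synthetases (median 0.32) and 1 of 18 cholesterol synthesis leaders (median 0.32). No member was called either way among 48 oxidative phosphorylation leaders (median 0.11), 24 histones (median 0.45, mean 0.25), 16 glycolysis leaders (median 0.13; ENO1 at 0.93 and called with the block, adjusted p = 0.0282) and 13 other TOP leaders (median 0.03; PABPC1 at 0.12). The 21 long nuclear non-coding RNAs and snoRNA hosts had a median of -0.20, with NEAT1 at -0.20, and 0 calls. No mitochondrially encoded RNA was in the files. Of 31 markers of other cell types 27 had a count, but only 2 features were tested and neither was called.

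Ribosomal protein leaders had 3 of 78 called for both rocaglates, RPL18 (2.42), RPL41 (1.91) and RPL24 (1.88), and adjusted over the list alone 7 rose and 4 fell. Of 7044 other leaders 96 rose (Fisher's exact odds ratio 2.89, p = 0.0941), and with the block 7 of 78 against 376 of 7044 (Fisher's exact p = 0.197). RPL18 was lost without DMSO library 2 or 3 (up to 0.0888), RPL41 without any 1 DMSO library (up to 0.185), and RPL24 without DMSO library 2 or 3, silvestrol library 1 or CR-1-31-B library 1 (up to 0.184). As a set they lay at -0.09 against 0.37 for other leaders (camera adjusted p = 0.00314; adjusted p = 0.952 with an estimated correlation). Their CDS (-0.29, 0.0330, with RPL41 alone called at 2.46) and the CDS of other TOP mRNAs (-0.62, 0.000317), oxidative phosphorylation (-0.36, 0.0173), chaperones (-0.49, 0.0173, with 2 lower adjusted over the list alone), glycolysis (-0.58, 0.00314) and cell cycle genes (-0.40, 0.00841) lay below other CDS features. For these CDS sets adjusted p = 0.845 to 0.952 with an estimated correlation. The call of RPL41 CDS was lost without DMSO library 2 or 3 (up to 0.0991). Of their abundant members, the CDS of EEF1A1 was at -0.87 (adjusted p = 0.188) and called with the block (0.0126), and EEF2 was at -0.64, GAPDH at -0.58 and ALDOA at -0.69 without a call. The 3'UTRs of initiation factors (-0.41, 0.0330) and of other TOP mRNAs (-0.67, 0.0467, and 0.0503 with the block, with 1 lower adjusted over the list alone) also lay lower, both with adjusted p = 0.845 with an estimated correlation. Sets above their class were the small non-coding RNAs (0.25 against -0.14, 8.5e-05), KRAB CDS (0.21, 0.00868) and 3'UTRs (-0.11 against -0.28, 0.0191), and immediate early leaders (0.0330), CDS (0.35, 0.00841) and 3'UTRs (0.02 against -0.27, 0.00601), with adjusted p = 0.845 to 0.952 with an estimated correlation. The last median changed sign with upper quartile scaling (-0.02). None of the 15 sets passed with fry. Without DMSO library 1, 3 sets passed, without silvestrol library 2, 8, and without CR-1-31-B library 3, 7. The other TOP and glycolysis CDS sets passed in all 9 such fits, and ribosomal protein leaders (0.436) and cell cycle CDS (0.236) failed without DMSO library 1 alone. Without that library the small non-coding RNAs were the only further set kept (the others from 0.0842 to 0.607). Of the rest, 5 failed without DMSO library 2 (0.0525 to 0.105), 5 without DMSO library 3 (0.0682 to 0.484), 7 without silvestrol library 2 (0.0833 to 0.307), 5 without silvestrol library 3 (0.0603 to 0.178), 4 without CR-1-31-B library 2 (0.0611 to 0.0977) and 8 without CR-1-31-B library 3 (0.0627 to 0.137).

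The fold changes of the compounds against the same DMSO libraries were compared to see how far their profiles coincide. Across 24713 features, which are not independent replicates, Pearson's r was 0.686, where simulated unchanged groups sharing the DMSO libraries gave 0.511 (0.503 to 0.520), and Spearman's rho 0.643 against 0.481. The covariance was 0.387 against a simulated 0.233, a difference of 0.154, and 74.2% of features had the same sign against 66.8%. Among leaders r was 0.741 against 0.512, and the covariance 0.526 against 0.245. Of the higher calls (63 and 71) 35 were shared, where independent lists would share 0.181 and the simulated groups shared 0. With the block 176 were shared of 308 and 348 (independent 4.34). The simulated values, also those without 1 library, leave out the effects and the pairing by number. The independent value leaves out the shared controls. With 3 DMSO libraries the controls could not be split, so part of the excess may come from them. Leaving out 1 library, r was 0.0724 to 0.212 above the simulated mean of the same setting, and the observed 0.504 without silvestrol library 1 stood against a simulated 0.432.

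**Figure D4:**
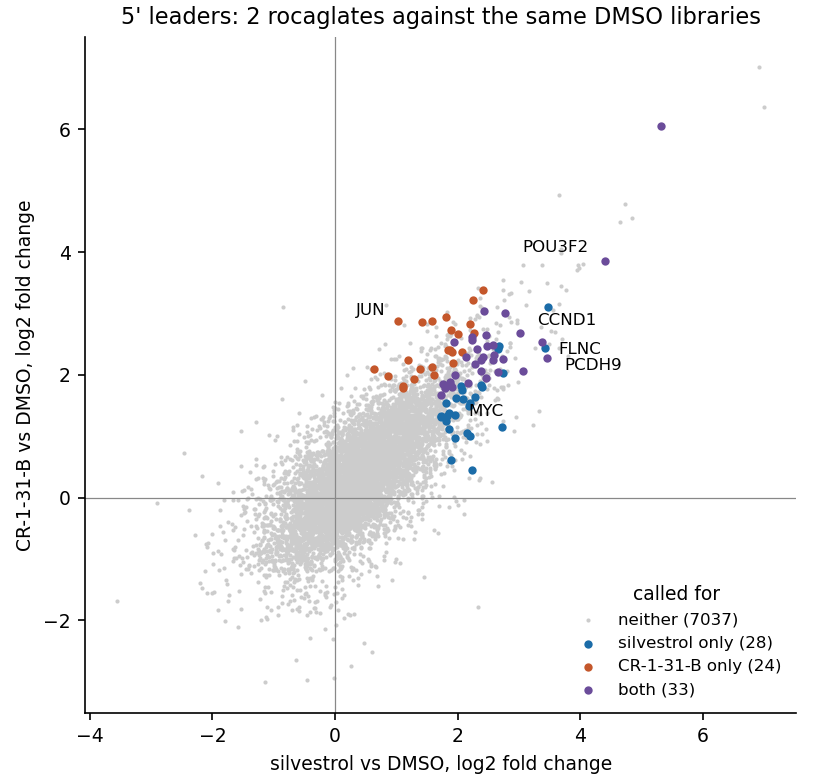
Log2 fold change of each of the 7122 tested 5' leaders with silvestrol (x axis) and with CR-1-31-B (y axis), both against the same 3 DMSO libraries, coloured by the contrast in which a leader was called. Called for both were 33 leaders, for silvestrol alone 28 and for CR-1-31-B alone 24, and JUN lay at 1.03 and 2.87.

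Rocaglates are known to clamp eIF4A onto polypurine RNA, and the question was whether purine-rich leaders gained more. The 1349 leaders with the highest density of all-purine 6-mers (at least 5.52 per 100 nt) had a median log2 fold change of 0.62 for both rocaglates, against 0.31 for the others, a difference of 0.31 (camera, adjusted p = 0.00221 over 48 sequence tests). Of the leaders with a sequence that rose, 40 were among these 1349 and 53 among the others, a far larger group that made up the rest of 6741. In 5 equal groups from the lowest density to the highest, 9, 8, 14, 22 and 40 leaders rose. For silvestrol the difference was 0.34 (adjusted p = 0.00222, with 31 and 24 leaders called) and for CR-1-31-B 0.29 (adjusted p = 0.00918, with 24 and 30 called). With the block the leaders called were 100 and 151 for silvestrol, 76 and 170 for CR-1-31-B and 126 and 242 for both. Spearman's rho across 6741 leaders between density and fold change was 0.212 for both rocaglates and 0.196 for CR-1-31-B. With an estimated correlation none of the 3 passed (p = 0.223, 0.225 and 0.289). All-pyrimidine 6-mers, a control chosen after the data but before its own result was seen, had a difference of -0.16 and were not called by camera. In CDS the same comparison gave a difference of 0.03, not called by camera. Features with GC-rich CDS lay higher with silvestrol by a median of 0.24 (camera adjusted p = 0.00452; adjusted p = 0.984 with an estimated correlation), and features with the longest CDS lay lower with CR-1-31-B (median difference -0.18) (camera adjusted p = 0.0246; adjusted p = 0.984 with an estimated correlation), whereas GC content and length of leaders were not called by camera with silvestrol (adjusted p = 0.729 and 0.867). For both rocaglates the median differences were 0.20 for GC-rich CDS and -0.15 for the longest CDS (camera adjusted p = 0.0153 and 0.0246; adjusted p = 0.984 with an estimated correlation).

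**Figure D5:**
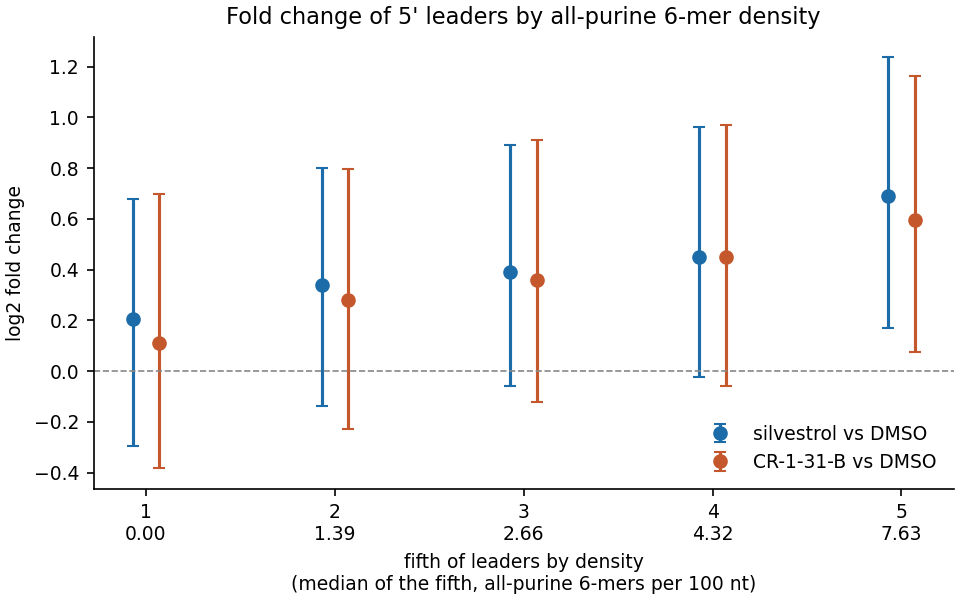
Median log2 fold change (points) and quartiles (bars) of 5' leaders in 5 equal groups by all-purine 6-mer density, for silvestrol and CR-1-31-B against DMSO; each group holds 1348 or 1349 leaders. The medians were 0.21 and 0.11 in the group of lowest density and 0.69 and 0.60 in the highest.

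Anti-FLAG DMSO against input asks what eIF4A binds before any rocaglate. There is 1 input library, so this comparison has no replicate check and describes these libraries. Leaders had a median log2 ratio of 1.59 (1.49 to 1.59 in the 3 DMSO libraries) with 89.2% of 4993 above 0, CDS -0.04, 3'UTRs 0.04 and ncRNA -0.10. With TMM factors these medians were 1.15, -0.50, -0.42 and -0.55, so the 3'UTR sign depends on the scaling. The MYC leader was at 107 ± 23.7 plain CPM (n = 3) against 19.6 in the input, and the JUN leader at 378 ± 173 against 165. The 10 highest ratios were those of MTRNR2L1 3'UTR (log2 7.96), HINT3 3'UTR (7.23; 40251 ± 13937 against 268 CPM), PLCG2 leader (6.82), KRT32 transcript (6.19; 1104 ± 33.9 against 14.1 CPM), SNORD75 (5.29), LINC01783 (5.29), 3 uncharacterised LOC genes (5.26 to 5.71) and SNORD45B, which had 0 counts in the input and was at least 73.9-fold above a floor of 3 counts. MTRNR2L1 and PLCG2 each rest on 1 input count, and the plain ratios were 791 (95% counting interval 142 to 31256) and 358 (64.2 to 14134). The lowest were mostly nuclear small RNAs, among them RNU2-1 (-6.09; 1978 against 134442 CPM), SNORA64 (-5.08), SNORA14A (-4.99), SNORA73B (-4.87), SNORA35B (-4.60) and SCARNA11 (-4.39), with 3 LOC genes (-10.51, -9.35 and -4.47) and the SIRT4 leader (-4.75).

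By list, leaders of oxidative phosphorylation genes had a median ratio to input at the 99.99 percentile of matched random lists, followed by chaperones (6.82, percentile 99.5), glycolysis (6.84, percentile 99.1), aminoacyl-tRNA synthetases (6.07, percentile 98.7) and ribosomal proteins (5.83, percentile 97.9). KRAB zinc finger leaders (1.60) and immediate early leaders (1.63, percentile 0.520) had the lowest percentiles, the KRAB median lying below all 10000 random lists. The CDS of oxidative phosphorylation genes (2.28) and histones (1.61) lay above all random lists, and the CDS of immediate early genes (0.653, percentile 0.0700) and KRAB genes (0.738, percentile 0.0600) near the bottom. Small nuclear and nucleolar RNAs had a median ratio of 0.682, below all random lists.

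EIF4A1 was listed at 0 counts in every class of all 10 libraries, so no value is given for it. EIF4A2 CDS was at 49.3 ± 12.4 CPM in DMSO, 35.0 ± 7.64 with silvestrol and 46.1 ± 5.80 with CR-1-31-B, and EIF4A3 CDS at 48.8 ± 9.90, 36.1 ± 13.9 and 36.4 ± 20.2 CPM (n = 3 each). No part of EIF4A2 or EIF4A3 was called in any contrast.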

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

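The comparison of larger libraries, that of the libraries numbered 3 and that with held-out DMSO libraries were tests chosen only after the results were seen. What was flagged is a difference between the compounds in the fit with the replicate block: the JUN 5' leader, at a log2 difference of 1.82 (edgeR adjusted p = 0.00292), and the immediate early genes as a set, with a median of 0.28 in leaders (camera adjusted p = 0.0149) and 0.91 in CDS (camera adjusted p = 0.00881). Without the block these medians were 0.31 and 0.71. For both sets adjusted p = 0.805 with an estimated correlation.

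For the JUN leader, more JUN mRNA after CR-1-31-B is a candidate explanation that the values leave open, since the JUN CDS and 3'UTR together were higher by 1.04 (SE 0.211). A single deviating library was excluded in the fit with the replicate block. There the lowest difference with any 1 of 9 libraries left out was 1.62. The call was kept in 9 of 9 (highest edgeR adjusted p = 0.0469). A stronger response of all leaders to CR-1-31-B was excluded, as the called leaders had a median difference of -0.10 between the compounds (SD 0.382). RNA levels were not measured here, so binding and abundance cannot be told apart.

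The higher counts on 5' leaders with both rocaglates were set against chance and against properties of the libraries. Among the 84 ways to divide 9 libraries into 6 and 3, the real one had the most calls in a fit of 2 groups (153, 1 of 84 reached it). The highest other, with 132 calls, set the 3 libraries numbered 2 against the rest, so the numbers also divide the libraries. Leaders made up 124 of the 153 calls and 44 of the 132. A random division of the libraries was excluded as the cause by the rule set for this test, at the smallest share that 84 divisions can give. The leader median was 0.39 in the real division and 0.50 in the highest other, with 3 of 84 at or above the real one, and within numbers 468 features were called against 1 in the highest other (1 of 27). The 3 rocaglate libraries smaller than the DMSO library of their number still gained 5.15 points of leader share (SD 3.43, lowest 2.10, highest 8.87). A gain was thus seen without a larger library. The 3 were close in size to those DMSO libraries (silvestrol library 2 held 1004145 counts against 1074588), so they cannot exclude library size as a cause. The larger libraries gained 10.4 points (SD 0.951, lowest 9.31), each more than any smaller one, so library size may contribute. Binding at polypurine leaders may contribute, but the difference of 0.31 between purine-rich and other leaders did not pass with an estimated correlation (camera p = 0.223), so the values cannot tell.

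The low leader share of CR-1-31-B library 3 could reflect a vehicle library under the wrong name, and its median of 1.25 over the leaders called for silvestrol cannot tell, since the same DMSO libraries chose those leaders and are centred there. Over 61 leaders chosen without 1 DMSO library, that held-out library stood at 0.14 to 0.64 above the mean of the other 2 and CR-1-31-B library 3 at 1.26 to 1.35. The lowest difference of the 3 was 0.71, against a range of 0.499 between the held-out libraries. This met the rule set for the test, but a rule set after the results and a range of 3 values cannot exclude a vehicle library. The lowest other rocaglate library stood at 2.05 to 2.18. CR-1-31-B library 3 thus lay above each held-out DMSO library and below every other rocaglate library. Conditions shared by the libraries numbered 3 may contribute: silvestrol library 3 gained 4.22 times as much leader share as CR-1-31-B library 3, but the low share of that library prompted this comparison, so it cannot tell. The cause of the low share was not found.

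For silvestrol against DMSO the 10 splits are too few for a share under 0.05 (real 63, highest other 1; 1 of 10). The same holds for CR-1-31-B against DMSO (real 72, highest other 0; 1 of 10) and for CR-1-31-B against silvestrol (real 0, highest other 0; 10 of 10).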

How the results depend on the processing

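No named call reversed its sign in the fits per feature in which it was tested, and its sign was not compared with counts summed per gene. Limma voom ended 15 named calls among 82 named results: POU3F2 and ZNF574 in 3 contrasts each, EIF4EBP1 and C6orf106 in 2, and SLC2A1, PSMC4, PSMD1, JUNB and IER2 in 1. Upper quartile scaling ended 2 named calls. Library size scaling, DESeq2, at least 50 counts on average and only the groups of the contrast ended 1 each. Without the libraries numbered 2, 26 of 82 named results lost their call, and without those numbered 3, 66 of 81. All calls without the replicate block were kept with it. Past the features, sets and counts given with it, the block moved no list, class or sequence test across the threshold. For silvestrol, CR-1-31-B, CR-1-31-B against silvestrol and both rocaglates, in this order, the calls were 215, 225, 7 and 320 without a filter beyond 1 count, 308, 335, 0 and 531 with DESeq2, and 316, 365, 1 and 505 with the block; the cause was not tested. At a threshold of 0.1 they were 113, 182, 0 and 275, by construction. With at least 50 counts on average 98, 139, 0 and 216 were called, with fewer features tested. Summed per gene, where the parts of a gene are added, 6, 8, 0 and 11 were called. The cause of this fall was not tested. Chosen after seeing the data, leaders alone gave 105, 103, 0 and 190. Without the libraries numbered 2 the counts were 93, 9, 0 and 58, and without those numbered 3, 0, 1, 0 and 2; the cause was not tested. Leaving out 1 library gave 4 to 100, 0 to 226, 0 to 0 and 7 to 287 calls, and 0 to 13, 6 to 15, 0 to 6 and 3 to 20 list sets. With an estimated correlation or with fry 0 sets passed in each contrast. CR-1-31-B against silvestrol had 2 sets with the block and 2 with at least 50 counts. With the classes of a list together, chosen after seeing the data, 4, 6, 1 and 3 passed in the order above; the cause was not tested. The correlation of the compounds was 0.504 to 0.753 without 1 library (simulated means 0.432 to 0.636) and 0.815 with at least 50 counts (simulated mean 0.503). The purine difference of leaders did not pass with an estimated correlation (camera p = 0.223 for both, 0.225 for silvestrol and 0.289 for CR-1-31-B), and without 1 library camera's p was at most 0.000913, 0.00178 and 0.00492 in the same order. The leader share gained 6.75 to 9.32 points for both, 6.32 to 9.27 for silvestrol and 5.03 to 11.1 for CR-1-31-B without 1 library. Without the HINT3 3'UTR counts, chosen after seeing the data, it gained 7.30 points for both (exact permutation p = 0.0595), since these counts leave the total. Against input, the leader median was 1.71 with a prior of 0.1 CPM, 1.15 with TMM, 1.67 with at least 50 counts in every library and 1.55 to 1.63 without 1 library. The 3'UTR median was -0.42 with TMM, 0.21 with at least 50 counts and -0.0368 (without DMSO library 3) to 0.10 without 1 library; the cause was not tested. Depth was not varied. On simulated counts of the same depth edgeR recovered 28 of 100 features changed 4-fold for silvestrol.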

Other observations

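The purine signal of leaders was looked at by tetramer. The tetramers whose density in leaders correlated best with the fold change for both rocaglates were GGAG (rho 0.295) and GAGC (rho 0.252), and 6 of the 10 highest were all-purine, where 16 of 256 tetramers are. Tetramers overlap, and the count of 6 cannot tell a preference for purines from other leader properties.

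The correlation of all-purine 6-mer density with the fold change was 0.211 in the real division of 9 libraries and 0.181 in the highest of the other 83, so that a random division was excluded as the cause (1 of 84). GC content, length and expression of leaders did not account for it in a linear model. Per SD of density the fold change was higher by 0.154 with these 3 in the model and by 0.152 without them. The SE of 0.0095 takes the 6741 leaders as independent, so it does not measure the spread between libraries. For CDS features, camera could not tell purine content from no effect, with a difference of 0.0255 between the purine-rich and the other coding sequences. In the linear model, however, the CDS fold change was higher by 0.0675 per SD of density (SE 0.00704) with GC content, length and expression included. Without these 3 it was higher by 0.0268 (SE 0.00663). A positive purine term was thus not limited to leaders, and these SEs too take the 8339 CDS features as independent.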
